A study of Mus musculus with 6 samples.

How the data were processed

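RNA was measured by sequencing in 6 libraries from mouse intestinal organoids of the Apc Min genotype. Per the labels, 3 libraries came from control medium and 3 from low glutamine medium, with libraries built with TruSeq kits from total RNA. The glutamine concentrations, the duration of the treatment, the part of the intestine and the animals were not given in the sources used here. The series' design text calls the samples of a group biological replicates. Nothing says whether they came from separate animals or from separate cultures of 1 line, so the p-values measure the spread between these samples.

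The deposited values are RPKM, a read number scaled to transcript length and library depth, made by the authors, with 1 column per library and 24956 rows named by gene symbol. The submitters' processing notes name CASAVA 1.8, HISAT2 2.0.4, Partek and the mm10 genome, with no role or order. The annotation, the counting rule and the strandedness were not given in the sources used here. The RPKM columns summed to between 327956 and 370158, and 26 symbols had been turned into dates by spreadsheet software, 2 of them in duplicate. Of the rows, 24309 matched a RefSeq gene of GRCm38.p6 (mm10) by symbol, 524 by a synonym and 97 not at all. Coordinates are 1-based RefSeq gene bounds on that build.

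RPKM values are not counts, and the transcript lengths used by the authors were not used here, so no count test was run. The depth was estimated from the lowest values: in genes with a single exon, the annotated length gives the value of 1 read. The estimates were 31.2, 35.4 and 24.4 M reads for control replicates 1 to 3 and 34.0, 32.9 and 28.3 M reads for low glutamine replicates 1 to 3. At these depths between 83.1% and 89.5% of the low values checked were whole reads within a tolerance of 0.02. The values checked include those that set the depth, 42 of 91 in control replicate 1, which are whole by construction. A transcript of 1 kilobase at 1 RPKM therefore rested on 24.4 to 35.4 reads per library, and low genes carry counting error of that order. Among genes under 0.3 RPKM, the most frequent ratio of RPKM to that of control replicate 1 was 0.88 to 1.28 across the other libraries. It agreed within 0.001 with the estimated depth of control replicate 1 divided by that of the library, so a deeper library has the lower ratio.

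The group test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with an empirical Bayes variance trend, for the 11082 genes with a mean of at least 1 RPKM over the 6 libraries. Rows below that limit, 13874 in number, were not tested. The tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, low glutamine over control, which understates the change of low genes. Gene lists were compared with all other tested genes by camera at a preset inter-gene correlation of 0.01, again with Benjamini-Hochberg adjustment over the 24 lists with at least 3 tested members. Beside it stand camera with an estimated correlation, the rotation test fry, and the count of members past the test, over all genes and adjusted over the list alone. With 6 libraries, camera with an estimated correlation has few degrees of freedom. A list that did not pass with it is not shown to be unchanged. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for the tables and plots.

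Before the data were examined, 27 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists covered Wnt/beta-catenin targets, stem cell, enterocyte, goblet, Paneth, enteroendocrine and tuft cell markers and fetal-like epithelium. They further covered amino acid response, tRNA synthetases, glutamine metabolism, TCA cycle, glycolysis, cholesterol synthesis, the unfolded protein response, DNA replication, mitosis, 2-oxoglutarate-dependent demethylases, p53, NRF2, interferon, autophagy, immediate early, mitochondrial, ribosomal, stromal and immune genes. Named were the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with no overlap between groups and at least 5 RPKM in the higher group, leaving out predicted gene and clone symbols. Up to 4 members with the smallest p from each list past the camera threshold, and 2 from every other list, were added, together with Axin2, Lgr5, Myc, Krt20, Fabp2, Alpi, Muc2, Asns, Glul and Apc. The rule gave 97 genes, of which some are not reported here. Other list members are named where they make up a small remainder or illustrate a list, and were then chosen after their values were seen.

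The groups share replicate numbers. Deviations from the group means correlated at 0.15, 0.25 and 0.57 between the same-numbered libraries 1, 2 and 3. This met the rule fixed for this check, every pair above 0.1. The rule cannot show that the numbers pair the samples, since replicates 1 and 2 exchanged also met it. Low glutamine replicate 1 correlated at 0.36 with control replicate 2, and low glutamine replicate 2 at 0.20 with control replicate 1. Whether the samples were paired stays open. The fit with the replicate number as a block is therefore given where it changes a call. Low glutamine replicates 1 and 2 differed by little more than counting noise. In genes with 50 to 1000, 1000 to 5000 and at least 5000 reads the median squared difference was 1.13, 1.26 and 1.47 times the counting noise. For the other pairs of a group it was 1.66 to 18.6 times. An excess over counting noise does not show that they are separate samples. They were kept as 2 samples, as the labels list them, and an alternative averages them. If they are not separate, the SDs of the low glutamine group rest on fewer samples than libraries.

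The fitting code was tested on simulated data for the comparison of low glutamine with control. Of 200 genes changed among 11082, 83.6% of those changed 1.5-fold, 97% of those changed 2-fold and 98.5% of those changed 4-fold were recovered. Of 195 calls, 9 were false. A planted list of 20 genes passed the camera threshold, and 0 of 20 lists without a change did. The simulated noise was independent between genes, while correlations estimated within the real lists were 0.11 to 0.62. The simulation therefore cannot show how often camera at the preset correlation calls real lists falsely. It also changed 200 genes, where 7361 passed in the data. Alternatives changed the pseudocount, the filter, the scaling between libraries, the variance model, the block, the correlation within lists and the libraries used.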

Results

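The data comprised RNA-seq of mouse intestinal organoids, self-organising cultures of intestinal epithelium, of the Apc Min genotype. Apc encodes a scaffold of the complex that degrades beta-catenin, and the Min allele carries a truncating mutation that predisposes mice to intestinal adenomas. Organoids in control medium (3 libraries) were compared with organoids in low glutamine medium (3 libraries). The series title places the comparison in a study of alpha-ketoglutarate, a metabolite downstream of glutamine, with Wnt signalling and differentiation as the readouts. Estimated depths were 24.4 to 35.4 M (mega) reads per control library and 28.3 to 34.0 M reads per low glutamine library. Libraries correlated at 0.996 to 0.998 within a group and at 0.922 to 0.927 between groups on the log2 scale (Pearson, across genes, which are not independent).

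In low glutamine libraries, 17 of 20 tested Wnt target genes, 17 of 19 stem cell markers and 14 of 15 Paneth cell markers rose. These libraries also differed from control in sex-linked transcripts, so no change here can be laid to the medium alone. Of the enterocyte markers 21 of 24 fell, of the goblet cell markers 11 of 13, of the TCA cycle genes 20 of 22 and of the cholesterol synthesis genes 23 of 24. By limma, 4001 of 11082 tested genes were higher and 3360 lower in low glutamine at an adjusted p under 0.05, together 7361 genes or 66.4% of those tested. Of these, 1031 were at least 1.5-fold higher and 1032 at least 1.5-fold lower, and 468 and 449 were at least 2-fold higher and lower. The 3 values of a group lay wholly above or below those of the other for 7781 genes, 70.2% of those tested, where chance gives 10%. Of the calls, 54.4% were higher in low glutamine. This share was 70.4% with each library rescaled to a common sum and 71.7% with the same done after the ribosomal RNA precursor Rn45s was left out. With median-of-ratios scaling it was 46.5%, so that more genes were lower (4149) than higher (3605). The rescalings to a common sum moved the median log2 fold change of all genes from 0.03 to 0.18 and 0.17, so small changes in either direction are relative to the scaling used.

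The libraries of the groups also differed in sex-linked transcripts. Xist, the non-coding RNA that silences an X chromosome (chromosome X, 103460373 to 103483233 of mm10), stood at 87.3 ± 3.78 RPKM (SD, n = 3) in control and 0.0286 ± 0.00577 RPKM in low glutamine. The Y-linked gene Eif2s3y (chromosome Y, 1010562 to 1049134) was listed at 0 in every control library and at 26.6, 25.2 and 31.4 RPKM in the low glutamine libraries. Kdm5d and Uty, also Y-linked, were listed at 0 in every control library and averaged 6.82 ± 0.457 and 4.60 ± 0.263 RPKM in low glutamine, and Ddx3y averaged 0.0104 ± 0.0126 and 9.51 ± 0.136 RPKM. Eif2s3y, Kdm5d and Uty were the 3 rows of the table at 0 in all controls and above 3 RPKM in all low glutamine libraries, and 0 rows showed the reverse. The medium and this difference coincided in all 6 libraries, and this holds for every gene group described here. Among autosomal genes, 7106 of 10720 (66.3%) passed the test.

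**Figure D1:**
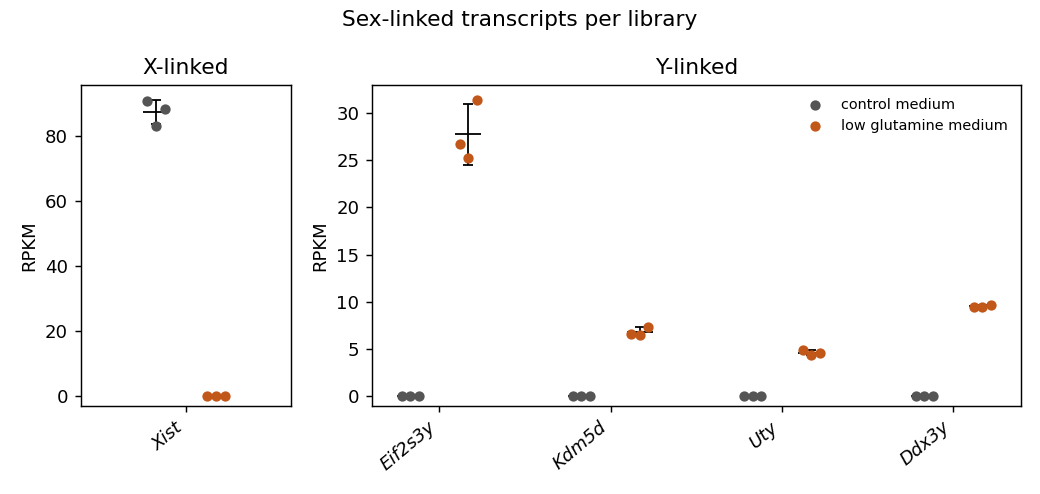
RPKM of Xist and of the Y-linked genes Eif2s3y, Kdm5d, Uty and Ddx3y in each of the 6 libraries (dots), with the group mean and SD (black, n = 3). Xist lay between 83.1 and 90.5 RPKM in the control libraries and at most 0.0350 RPKM in the low glutamine libraries, and the Y-linked genes showed the reverse.

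Targets of Wnt/beta-catenin signalling were higher in low glutamine. Axin2, a negative feedback target of the pathway (chromosome 11, 108917828 to 108950783), rose from 48.8 ± 1.96 to 111 ± 2.51 RPKM (log2 fold change 1.17 ± 0.05 SE, limma adjusted p = 1.8e-09). The stem cell receptor Lgr5 (chromosome 10, 115450314 to 115587780) rose from 42.5 ± 1.14 to 113 ± 3.87 RPKM (1.39 ± 0.05, adjusted p = 3.2e-10). Nkd1, Prox1 and Cd44 rose from 0.457, 0.604 and 4.20 RPKM to 13.7, 5.77 and 27.7 RPKM, and Tnfrsf19 from 1.24 to 45.9 RPKM. Myc, a growth regulator, measured 43.0 ± 2.03 and 46.9 ± 1.22 RPKM (0.13 ± 0.05, adjusted p = 0.062). Of 20 tested targets, 17 rose and 0 fell (18 and 0 adjusted over the list alone, 18 and 1 with quantile normalization). Besides Myc, Ccnd1 (14.7 RPKM in both groups) and Kremen1 (6.72 and 6.32 RPKM) did not pass. The median log2 fold change was 1.05, with a camera adjusted p of 2.5e-08 and an adjusted p = 0.29 with an estimated correlation. It ran from 0.69 with a pseudocount of 5 to 1.23 with rescaling to a common sum. Myc passed the test as higher with libraries rescaled to a common sum (0.25), quantile normalised (0.26) or rescaled without Rn45s (0.28), with an adjusted p from 1.3e-04 to 0.17 over the alternatives. Apc itself measured 12.9 ± 0.294 and 16.7 ± 1.22 RPKM (0.35 ± 0.06, adjusted p = 2.1e-04), a value that does not separate the Min from any wild-type allele.

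Intestinal stem cell markers moved the same way, and 8 of their genes are also Wnt targets. Of 19 tested markers 17 rose, with the same counts adjusted over the list alone. Msi1, an RNA-binding protein of stem cells, rose from 8.39 ± 0.442 to 19.1 ± 0.608 RPKM, and Olfm4, an abundant marker of crypt base cells, from 453 to 897 RPKM. The water channel Aqp4 fell by 0.36 on the log2 scale, and Hopx (103 and 110 RPKM) did not pass. The list median was 0.82, with a camera adjusted p of 1.3e-06 and an adjusted p = 0.32 with an estimated correlation. Replicate 3 of both groups deviated in a shared direction. The median of the Wnt targets was 1.12 in the replicate 3 pair and 1.02 in the others, and that of the stem cell markers 0.87 and 0.79.

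**Figure D2:**
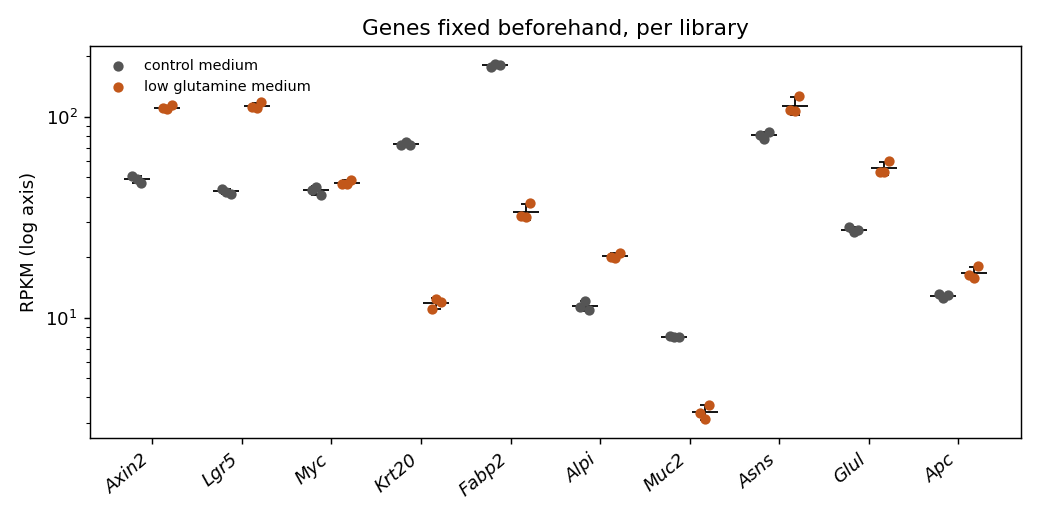
RPKM on a log axis of 10 genes fixed before the data were examined, in each of the 6 libraries (dots), with the group mean and SD (black, n = 3). Axin2 and Lgr5 lay above 100 RPKM in every low glutamine library, while Krt20 averaged 72.9 RPKM in control and 11.8 RPKM in low glutamine.

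Enterocyte markers, the genes of the absorptive cells that make up most of the differentiated epithelium, were lower in low glutamine. Krt20, a keratin of differentiated cells (chromosome 11, 99428385 to 99438153), fell from 72.9 ± 1.63 to 11.8 ± 0.684 RPKM (-2.53 ± 0.06, adjusted p = 1.9e-12). The fatty acid binding protein Fabp2 fell from 180 ± 2.95 to 33.7 ± 3.10 RPKM and the disaccharidase Sis from 422 ± 12.4 to 39.8 ± 1.83 RPKM. Lactase (Lct) and the fructose transporter Slc2a5 fell by 3.51 and 2.70 on the log2 scale. Of 24 tested markers, 21 fell and 3 rose, with the same counts adjusted over the list alone. The 3 that rose were the alkaline phosphatase Alpi (11.4 ± 0.621 to 20.3 ± 0.629 RPKM, adjusted p = 8.9e-08), the aminopeptidase Anpep (220 to 466 RPKM) and the apolipoprotein Apob (33.1 to 40.5 RPKM). The list median was -2.55 (-2.45 in the replicate 3 pair and -2.59 in the others), with a camera adjusted p of 1.1e-11 and an adjusted p = 0.29 with an estimated correlation.

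Markers of mucus-secreting goblet cells were also lower: 11 of 13 fell, 1 rose and 1 did not pass, with the same counts adjusted over the list alone. Muc2, the main gel-forming mucin, fell from 8.03 ± 0.0614 to 3.38 ± 0.289 RPKM (-1.05 ± 0.06, adjusted p = 1.1e-08). Fcgbp, Guca2a and Zg16 fell by 1.67, 2.73 and 1.93 on the log2 scale. The transcription factor Atoh1, needed for secretory cells, fell from 5.37 to 2.98 RPKM. Creb3l1 rose by 0.30, and Klk1 stood at 3.69 and 3.55 RPKM. The median was -1.05 (camera adjusted p = 1.0e-05, adjusted p = 0.29 with an estimated correlation), and -1.10 to -0.64 over the alternatives.

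Paneth cell markers, the antimicrobial products of the secretory cells beside crypt stem cells, were higher. Of 15, 14 rose and 1, Nupr1, fell, with the same counts adjusted over the list alone. The matrix protease Mmp7 rose from 21.4 ± 0.662 to 108 ± 5.46 RPKM, the protease Habp2 from 2.88 ± 0.109 to 20.7 ± 1.24 RPKM and lysozyme (Lyz1) from 310 to 462 RPKM. The defensins Defa30 and Defa5 rose from 43.2 ± 4.96 and 0.976 ± 0.356 to 899 ± 77.8 and 44.2 ± 8.14 RPKM. Defensin genes are near-identical copies on chromosome 8, so the assignment of reads to a single copy is uncertain. The list median was 2.48 (camera adjusted p = 1.3e-06, adjusted p = 0.29 with an estimated correlation).

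Enteroendocrine markers, the genes of the hormone-secreting cells, went mostly up. Neurog3, the transcription factor that starts this lineage, rose from 8.72 ± 0.299 to 46.7 ± 0.546 RPKM, and the granule protein Chgb from 139 ± 6.77 to 886 ± 94.1 RPKM. Tac1 and ghrelin (Ghrl) rose by 2.73 and 2.04. Of 17 tested markers 14 rose and 3 fell, with the same counts adjusted over the list alone. The 3 that fell were the hormone genes Gcg (84.8 ± 8.03 to 16.1 ± 2.0 RPKM), Pyy (5.93 ± 1.01 to 1.35 ± 0.339 RPKM) and Nts (5.93 ± 0.905 to 0.110 ± 0.0781 RPKM). The median was 1.70 (camera adjusted p = 5.5e-05, adjusted p = 0.32 with an estimated correlation), and 1.12 to 2.01 over the alternatives. Of 5 tested tuft cell markers, genes of a chemosensory cell type, 4 rose and Il17rb fell. Pou2f3 and Avil rose from 1.05 and 0.708 to 2.88 and 1.87 RPKM, but the list did not pass (median 0.60, camera adjusted p = 0.13).

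Genes of fetal-like and regenerating epithelium were higher: 10 of 11 tested members rose. Clu rose from 0.440 ± 0.103 to 35.2 ± 1.24 RPKM, Anxa1 from 0.652 ± 0.254 to 40.3 ± 2.38 RPKM and Ly6a, which encodes the surface protein Sca-1, from 0.975 ± 0.493 to 29.9 ± 1.71 RPKM. Msln rose from 0.210 to 4.54 RPKM, and Krt7, with a higher control level, from 47.1 to 101 RPKM. The growth factor gene Areg fell from 41.2 to 26.9 RPKM. The median was 1.99 (camera adjusted p = 7.9e-06, adjusted p = 0.29 with an estimated correlation). It ran from 1.03 with a pseudocount of 5 to 2.56 with a pseudocount of 0.1, and was 1.05 without a filter on low values.

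**Figure D3:**
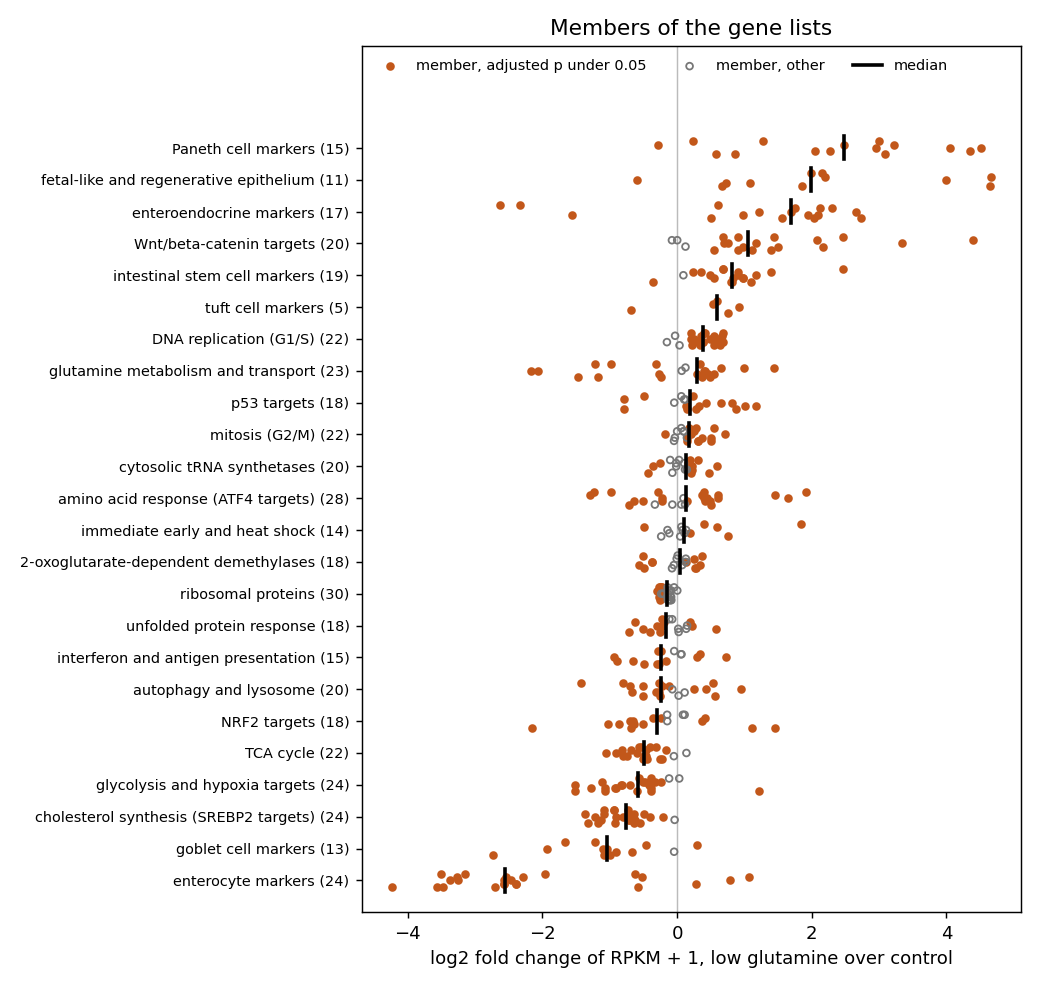
Log2 fold change of RPKM + 1, low glutamine over control, for the tested members of each of the 24 gene lists (number of members in brackets), with filled dots for members past the test and a black bar for the median. Medians ran from -2.55 for enterocyte markers to 2.48 for Paneth cell markers. The medians of the ribosomal proteins and of the demethylases lay near 0 and changed sign under some scalings.

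Among the genes with the largest rises were digestive and secreted proteins. Reg1, a secreted lectin (chromosome 6, 78425983 to 78428668), rose from 0.157 ± 0.00995 to 59.2 ± 4.64 RPKM (log2 fold change 5.70 ± 0.06), and Pgc, the gastric protease precursor progastricsin, from 0.197 ± 0.122 to 59.9 ± 3.57 RPKM (5.67 ± 0.07). Igfbp2, an insulin-like growth factor binding protein, rose from 2.82 ± 0.0888 to 112 ± 3.20 RPKM. Defa23 and Defa31, again of the near-identical defensin family, rose by 4.89 and 4.88. Anxa1, Clu, Defa5, Tnfrsf19 and the Y-linked Eif2s3y completed the 10. The largest falls included Xist. Among them were also the chymotrypsinogen Ctrb1, the trypsin inhibitor Spink1, the cytochrome P450 Cyp3a25, the guanylin-family peptide Guca2b and the glutamyl transferase Ggt1. They fell by 3.97, 3.94, 3.96, 3.94 and 3.85. Naaladl1, Npl and the transcription factor Osr2 fell by 4.03, 4.0 and 4.0.

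Genes of glutamine metabolism and transport moved in both directions, in libraries that differ in medium glutamine. Glul, glutamine synthetase (chromosome 1, 153899929 to 153909723), rose from 27.4 ± 0.758 to 55.4 ± 4.25 RPKM (0.99 ± 0.06, adjusted p = 2.8e-08). The neutral amino acid transporter Slc6a19 and the alanine transaminase Gpt fell by 2.17 and 2.07, and the transporter Slc1a4 rose from 13.2 to 37.5 RPKM. Of 23 tested members, 12 rose, 9 fell and 2 did not pass, with the same counts adjusted over the list alone. The median (0.30) and the mean (-0.13) differed in sign, and the list did not pass (camera adjusted p = 0.78).

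The amino acid response, the ATF4 target genes induced when amino acids are short, was likewise mixed. Asns, asparagine synthetase, rose from 80.7 ± 3.02 to 113 ± 11.3 RPKM (0.48 ± 0.07, adjusted p = 7.5e-05). The amino acid transporter Slc7a5 rose from 17.1 ± 0.469 to 67.2 ± 4.54 RPKM and Chac1 from 2.89 to 11.2 RPKM, while Cth, Ddit3 and Atf5 fell by 1.29, 1.23 and 0.98. Of 28 tested targets 14 rose and 9 fell (median 0.13, camera adjusted p = 0.43), and 18 rose and 7 fell with rescaling without Rn45s. Of 20 cytosolic tRNA synthetases 9 rose and 3 fell (median 0.13, camera adjusted p = 0.38), with Vars and Lars higher by 0.59 and 0.48. With rescaling to a common sum 15 synthetases rose and 3 fell. The synthetase list passed as higher after quantile normalization (adjusted p = 0.0053, and up to 0.67 over the alternatives).

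Enzymes of central carbon metabolism were lower. In the TCA cycle 20 of 22 members fell and 0 rose (16 and 1 with quantile normalization). Citrate synthase (Cs) fell from 205 ± 7.59 to 109 ± 3.99 RPKM, malate dehydrogenase Mdh2 from 492 ± 28.3 to 236 ± 2.17 RPKM, and Ogdh by 0.82 on the log2 scale. Idh2 and Suclg2 did not pass, at 76.7 and 42.3 RPKM in control and 84.7 and 41.0 RPKM in low glutamine. The median was -0.49 (camera adjusted p = 1.3e-06, adjusted p = 0.48 with an estimated correlation), and -0.55 to -0.30 over the alternatives. Of 24 glycolysis and hypoxia genes, 21 fell and 1, the hexokinase Hk2, rose (5.59 ± 0.309 to 14.4 ± 1.31 RPKM). The lactate exporter Slc16a3, the phosphofructokinase Pfkp and the hypoxia-responsive Ndrg1 fell by 1.51, 1.27 and 1.52. The list median was -0.58 (camera adjusted p = 4.0e-07, adjusted p = 0.48 with an estimated correlation).

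Cholesterol synthesis genes, targets of SREBP2, were lower with 23 of 24 below control and 0 above. Hmgcs1, which makes the precursor of mevalonate, fell from 308 ± 11.5 to 132 ± 1.44 RPKM and the sterol sensor partner Insig1 from 231 ± 11.7 to 92.1 ± 1.94 RPKM. Fdps and Pmvk fell by 1.17 and 1.08. Srebf2, which encodes SREBP2, did not pass (60.4 and 58.8 RPKM). The median was -0.76 (camera adjusted p = 1.4e-10, adjusted p = 0.29 with an estimated correlation). The counts for the TCA cycle, glycolysis and cholesterol lists were the same adjusted over the list alone.

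Proliferation genes were modestly higher. Of 22 DNA replication genes 19 rose and 0 fell, among them the helicase subunits Mcm2, Mcm3, Mcm4 and Mcm6, which rose by 0.68, 0.64, 0.68 and 0.66. The median was 0.38 (camera adjusted p = 1.8e-04, adjusted p = 0.55 with an estimated correlation). Of 22 mitotic genes 14 rose and 1, Birc5, fell. These counts moved to 19 and 0 with rescaling to a common sum, 21 and 0 with rescaling without Rn45s and 11 and 0 without low glutamine replicate 1. Mki67, the proliferation antigen, rose from 29.7 ± 1.29 to 42.5 ± 3.11 RPKM, and Cenpf, Top2a and Kif23 rose by 0.71, 0.54 and 0.50. The mitotic median was 0.18 (camera adjusted p = 0.019, adjusted p = 0.63 with an estimated correlation), and the list did not pass with the replicate number as a block (adjusted p = 0.26, and from 4.1e-04 to 0.26 over the alternatives). Counts for both lists were the same adjusted over the list alone.

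Demethylases that use 2-oxoglutarate, another name of alpha-ketoglutarate, showed no common direction. Of 18 tested genes 6 rose and 5 fell, and 10 rose and 5 fell with rescaling without Rn45s. With the fit on autosomal genes alone, 6 of 15 rose and 3 fell. The X-linked Kdm5c and Kdm6a, both lower in low glutamine, are not in that fit. Kdm3a fell from 32.1 ± 0.319 to 22.3 ± 1.40 RPKM and the X-linked Kdm5c from 16.6 ± 0.209 to 11.0 ± 0.727 RPKM. The median (0.04) and the mean (-0.02) differed in sign and the median was -0.01 with median-of-ratios scaling (camera adjusted p = 0.88). Among 18 p53 targets 11 rose and 3 fell (12 and 3 adjusted over the list alone, 14 and 3 with rescaling without Rn45s, 9 and 3 with median-of-ratios scaling). Eda2r and Plk2 rose by 1.17 and 1.01, while Cdkn1a, the cell cycle inhibitor p21, fell from 83.0 to 47.6 RPKM. The p53 list did not pass (median 0.19, camera adjusted p = 0.082), except with genes of at least 5 RPKM (adjusted p = 0.045, and up to 0.26 over the alternatives).

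Stress and immune response genes gave mixed counts. Of 18 NRF2 targets, genes of the oxidative stress response, 4 rose and 10 fell (4 and 11 adjusted over the list alone). The malic enzyme Me1 fell from 21.4 ± 1.13 to 4.04 ± 0.218 RPKM and the cystine transporter Slc7a11 rose from 1.27 ± 0.0704 to 5.23 ± 0.112 RPKM. The list lay close to the threshold (median -0.30, camera adjusted p = 0.054) and passed without control replicate 1 (adjusted p = 0.047) or control replicate 3 (adjusted p = 0.048), as it did in 8 of 20 alternatives (adjusted p 0.0065 to 0.29). Of 15 interferon and antigen presentation genes 3 rose and 9 fell, with Stat2 and Irf7 lower by more than the spread between replicates (8.15 and 4.0 RPKM in control, 3.76 and 1.68 RPKM in low glutamine). Autophagy and lysosome genes counted 5 higher and 12 lower of 20, among them Rragd and Hexa, which fell by 1.42 and 0.81. Medians were -0.24 for both lists (camera adjusted p = 0.11 and 0.096), and both passed as lower with rescaling to a common sum (adjusted p = 0.034 and 0.036). Over the alternatives these ran from 0.019 to 0.32 and from 0.0085 to 0.32. Of 18 unfolded protein response genes 3 rose and 9 fell (median -0.16, camera adjusted p = 0.15, and from 0.036 without a filter on low values to 0.90), with Herpud1 higher by 0.58 and Edem1 lower (-0.71). That balance depended on the scaling: 6 rose and 6 fell with rescaling to a common sum and with quantile normalization, and 7 rose and 5 fell with rescaling without Rn45s. Of 14 immediate early and heat shock genes 5 rose and Zfp36 fell (median 0.10, camera adjusted p = 0.28), and 10 rose and 1 fell with rescaling without Rn45s. Jun rose from 18.8 to 32.3 RPKM and Ier3 from 5.28 to 21.5 RPKM.

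Markers of other cell types were low in every library. None of the 15 stromal markers reached the mean of 1 RPKM needed for testing, with Postn the highest at 0.0394 RPKM in control and 0.827 RPKM in low glutamine. Of 13 immune markers 1 was tested, the macrophage gene Cd68, which rose from 0.685 ± 0.113 to 2.0 ± 0.188 RPKM (adjusted p = 1.0e-06). The 13 mitochondrially encoded mRNAs were not analysed here. Of 30 ribosomal protein genes 11 fell and 0 rose (9 and 0 adjusted over the list alone), a count that moved with the libraries and the scaling. Without control replicate 1 or 2 it was 4 or 3 lower, without low glutamine replicate 1 or 2 it was 7, and without low glutamine replicate 3 it was 23, with 0 higher in each. Median-of-ratios scaling gave 24 lower and 0 higher, rescaling to a common sum 3 and 0, rescaling without Rn45s 3 and 1, and quantile normalization 0 lower and 5 higher. Rpl8 and Rps20 fell by 0.29 and 0.27, and Rps3 and Rpl18 by 0.25 and 0.26. The median was -0.14 (camera adjusted p = 0.013, adjusted p = 0.63 with an estimated correlation). That list did not pass with the replicate number as a block (adjusted p = 0.32) or without low glutamine replicate 1 (adjusted p = 0.062), with a range of 1.2e-05 to 0.79 over the alternatives. Its median was 0.01 with quantile normalization, where the list did not pass (adjusted p = 0.79), and with rescaling without Rn45s. None of these 4 genes passed after quantile normalization, and Rpl18 no longer passed without control replicate 2 (adjusted p = 0.054, and from 1.9e-05 to 0.11 over the alternatives). The ribosomal RNA precursor Rn45s, a measure of leftover ribosomal RNA, ran from 1898 to 6680 RPKM in control and from 6788 to 12252 RPKM in low glutamine (1.65 ± 0.38, adjusted p = 0.0021). The values of 6680 and 6788 RPKM are those of replicate 3 of each group, so the difference lay in replicates 1 and 2.

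Across the 24 testable lists, 13 passed the camera threshold, 0 passed with an estimated correlation (adjusted p from 0.29 to 0.95) and 11 passed with the replicate block. Over the alternatives the mitotic median ran from 0.12 to 0.33. Of the lists that did not pass, the median of the tuft cell markers ran from 0.17 to 1.04, of glutamine metabolism from 0.13 to 0.45, and of the amino acid response and the tRNA synthetases from 0.07 to 0.28. It ran from -0.43 to -0.10 for the NRF2 targets, from -0.49 to -0.04 for the interferon genes, from -0.30 to -0.10 for autophagy and from -0.22 to -0.01 for the unfolded protein response. For the p53 targets it was 0.14 to 0.34 and for the immediate early genes 0.04 to 0.24. The rotation test fry, which compares a list with no other genes, gave 21 lists moving on balance in a shared direction and 24 with change in either direction.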

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

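The alternatives that left out Rn45s, kept replicates 1 and 2 of both groups, averaged low glutamine replicates 1 and 2, or kept autosomal genes were chosen after seeing the data, and the others before. A count test was not run, because whole reads cannot be recovered from RPKM without the transcript lengths. The median log2 fold changes of the Wnt targets, stem cell markers and enterocyte markers kept their direction and their side of the threshold in all settings but 1. With an estimated correlation their adjusted p was 0.29, 0.32 and 0.29 at medians of 1.05, 0.82 and -2.55, and 0 lists passed. The estimates were 0.11 to 0.62 over the 24 lists, above the preset 0.01, and widen the error of every list. The camera p-values at the preset correlation thus rest on nearly independent genes within a list. The estimates in turn rest on few residual degrees of freedom, so that form of camera could call little. Even the defensin genes (Defa), with 22 of 23 higher and a median of 2.50, had a camera adjusted p of 0.98 with it. Requiring a 1.5-fold change left 2063 genes, 1031 higher and 1032 lower, by construction. The number of higher genes was 2532 with a mean of at least 5 RPKM, where fewer genes are tested, 6384 after rescaling to a common sum, where the limit of 1 lets 12376 genes in, and 6041 after rescaling without Rn45s. Both scalings raise low glutamine values relative to control values. With the replicate block 7736 genes passed, 7321 of them shared with the fit without it, and among the lists and the named genes the block changed no call other than those of the mitotic and ribosomal lists. Without replicate 3 of either group 7908 genes passed, and with low glutamine replicates 1 and 2 averaged 6839. With the fit repeated on autosomal genes alone 7118 passed, against 7106 autosomal genes in the fit of all genes. Leaving out each library in turn gave 6651 to 7298 genes. The medians were then 0.92 to 1.13 for Wnt targets, 0.80 to 0.85 for stem cell markers and -2.58 to -2.51 for enterocyte markers. The median of the ribosomal proteins reversed to 0.0070 with quantile normalization and 0.012 without Rn45s, and that of the demethylases to -0.012 with median-of-ratios scaling. The cause was not tested beyond the scalings. Named genes reversed in 0 of 1927 combinations of gene and setting, lost their call in 7 and gained it in 3, all for Myc. Most of the named genes were chosen for a large change or a small p in these same libraries. Few lost calls are thus built into the choice. Lists lost a call in 4 of 479 combinations, the estimated correlation aside, and gained it in 18. The tuft cell list had too few genes for a value at a mean of at least 5 RPKM. Depth limits transcripts near 1 RPKM, where a kilobase rests on 24.4 to 35.4 reads.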

Other observations

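The gene families, single genes and tests of explanations described here were chosen after the data were seen, apart from the other splits of the samples. Among 175 families of at least 8 tested genes with a shared symbol start, 23 passed camera and 0 did with an estimated correlation, where the smallest adjusted p was 0.976. This covers each family named here. Of the Cox genes, for subunits and assembly factors of respiratory complex IV, 20 of 22 fell and 1 rose (median log2 fold change -0.45, camera adjusted p = 3.0e-04, adjusted p = 0.98 with an estimated correlation). Of the complex I genes, 11 of 14 Ndufa, 10 of 10 Ndufb and 7 of 8 Ndufs genes fell and 0 rose, with medians of -0.42, -0.41 and -0.41 (adjusted p = 0.0087, 0.013 and 0.029, and 0.98 for each with an estimated correlation). Cytochrome P450 genes (Cyp), which oxidise drugs and steroids, fell in 25 of 31 cases and rose in 5 (median -1.43, adjusted p = 6.6e-09, and 0.98 with an estimated correlation). Of 19 nucleoporin genes (Nup) 16 rose and 1 fell (median 0.34, adjusted p = 0.0087, and 0.98 with an estimated correlation). Medians of these 6 families kept their sign under every scaling.

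Single transcription factors of the intestine moved in both directions. Hnf4g, a nuclear receptor of enterocytes, fell from 40.6 ± 2.17 to 10.9 ± 0.277 RPKM (SD, n = 3), Hnf4a from 181 ± 4.59 to 128 ± 4.84 RPKM, and the homeobox genes Cdx1 and Cdx2 by 0.58 and 0.56 on the log2 scale. Pdx1, a regulator of duodenum and pancreas, rose from 0.302 ± 0.15 to 14.6 ± 0.389 RPKM, Onecut2 from 3.75 ± 0.131 to 15.2 ± 0.312 RPKM and Sox21 from 0.728 ± 0.0695 to 13.2 ± 1.0 RPKM. The antimicrobial lectins Reg3b and Reg3g rose by 3.35 and 3.03, and the metallothioneins Mt1 and Mt2 fell by 1.35 and 1.20. Bile acid and vitamin transport genes of the distal intestine, Slc10a2, Slc51a, Slc51b and Cubn, were lower, at log2 fold changes of -2.12, -1.28, -2.67 and -1.61. All of these passed limma at an adjusted p under 0.05 with the same sign under every scaling.

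The separation of the groups by Xist and Y-linked transcripts argues against cultures from 1 animal or line in both groups. Cultures from animals of different sex would give it, while a change of medium adds no Y-linked genes. With 0 libraries out of place, the highest sum of the 4 Y-linked genes in a control library was 0.0244 RPKM and the lowest in a low glutamine library 45.5 RPKM. Their X-linked partners Eif2s3x, Kdm5c, Kdm6a and Ddx3x, which escape X inactivation, had a median of -0.46 against 0.12 for the other 315 tested X-linked genes, although Ddx3x alone did not pass (0.03, adjusted p = 0.70). With 0 groups holding libraries of both patterns, the origin of the cultures and the medium cannot be told apart for any gene other than these sex-linked ones. The design confounds them.

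Paneth markers rose while goblet and enterocyte markers fell. Reads shared among near-identical defensins are argued against as the whole source of the Paneth rise: 7 of the 8 Paneth markers outside that family rose, with a median of 1.57 ± 0.58 (SE). For the defensins themselves, the sharing of reads was not tested. A loss of enterocytes that raises every other cell type alike would raise the goblet markers too. The goblet median of -1.05 ± 0.27, which lies 3.53 ± 0.56 below the Paneth median, argues against it. These are the values that showed the pattern, so this is no separate test. The SEs treat the genes of a list as independent. A shift in cell fate under low glutamine and the difference between the cultures of origin both stay open as causes of this pattern, untested.

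Enteroendocrine hormones moved both ways. A change in the number of these cells alone would move every marker of the list the same way. It is argued against as the whole cause. Of the 17 tested markers, 3 passed in the direction opposite to the list median of 1.70. A share of 0.05 of these 17 is 0.85, a yardstick that the adjusted threshold over all genes does not fix for a single list. The 3 falls are the values that showed the pattern, so this is no separate test. A change in the mix of enteroendocrine subtypes was not tested. As Gcg, Pyy and Nts and the bile acid genes belong to the distal intestine, another candidate explanation is ileum in the control and proximal intestine in the low glutamine cultures. Gata4, which is absent from the distal ileum, argues against distal ileum in the control cultures, at 38.1 to 45.2 RPKM in all libraries and a log2 fold change of -0.024 ± 0.064. The ileal gene Fabp6 did not exceed 0.401 RPKM. Pdx1, the regulator of duodenum, at 0.302 RPKM in control and 14.6 RPKM in low glutamine, and the lower bile acid genes go the other way. A difference in position thus stays open. A smaller shift in position along the intestine, and an effect of the medium on hormone genes, were not tested.

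The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and 4 of these part all same-numbered pairs. The real split gave 7361 changed genes, and the highest of the other splits 0, so 1 of 10 splits reached that count. For the medians of the Wnt targets, stem cell and enterocyte markers, the real values of 1.05, 0.82 and 2.55 (absolute) compare with at most 0.46, 0.32 and 0.91 in other splits, or 0.42, 0.29 and 0.91 among those that part all pairs. In each of these, 1 of 10 splits reached the real value. Every other split mixes libraries of both groups on each side. Any strong group difference, one of sex or culture included, thus gives smaller medians and fewer changed genes there by construction. The comparison therefore cannot tell the medium from the origin of the cultures. The number of lists past the camera threshold does not set the real split apart: it was 13, the other splits gave 10 to 14, and 4 of 10 splits reached 13.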
